A study of Mus musculus with 5 samples.

How the data were processed

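Islets picked by hand from 5 NOD.SCID mice, which carry the scid mutation of Prkdc and so lack mature T and B cells, were dissociated with trypsin, and the cells of each mouse were sequenced as 1 droplet library (10x Genomics 3 prime chemistry). The deposited matrices held raw UMI counts per Ensembl gene and cell barcode, with 32285 genes in each. Per the submitters' processing notes the authors used Cell Ranger 4.0.0 and the mm10 build; the annotation release and the settings of the cell calling were not stated. The lowest total of a barcode was 500 or 501 UMIs in every matrix. Gene coordinates and symbols came from a GRCm38 annotation, in which 32158 of the genes had a symbol.

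Mice were grouped by the diet label, 3 on chow and 2 on 20% hydrolyzed casein (HC). The library of HC mouse 2 was titled as chow-fed, but its diet label gave HC and the series design counts 3 chow and 2 HC mice, so it was kept as HC and the title's grouping was tried as an alternative. Library names began with FUN (chow mouse 1, HC mouse 1) or SKY (chow mice 2 and 3, HC mouse 2), and the labels do not say what the prefix marks. A model with prefix, age in weeks and diet had 4 columns and rank 3, so these terms could be tried only 1 at a time. Replicate numbers do not pair the mice. As a check for duplicated libraries, the chi-square per degree of freedom between 2 mice, over all kept cells, was 11.2 for the closest pair (chow mice 2 and 3). Over beta cells the closest pair was chow mouse 3 and HC mouse 2 (4.56), with 5.59 for chow mice 2 and 3. Xist was present and Y-linked transcripts were near 0 in the 5 libraries alike, so sex could not reveal a mix-up.

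Barcodes with at least 1000 UMIs, at least 500 detected genes and at most 15% mitochondrial UMIs passed. Scrublet, as run inside scanpy 1.11.5 per mouse with an expected rate of 6%, called 14 barcodes doublets (0.062%), so doublet detection did not work here. Droplets with RNA of 2 cell types are therefore still present, and an alternative without the 6% of highest doublet scores per mouse was added after the data were seen. The 22744 kept cells were scaled to 10000 UMIs, log-transformed and reduced over 2000 variable genes to 30 principal components. They were clustered with the Leiden method (igraph 0.11.9, resolution 1, exact search of 15 neighbours) into 20 clusters. A cluster was named when at least 3 markers of a type stood among its 10 leading genes, at 2 times or more the number of any other type, and no hormone of another endocrine type reached 50% of its highest cluster level. The markers had been fixed in advance; this naming rule was set after the clusters were seen and before any test of diet. Unnamed clusters held 9.11% ± 2.32 of cells in HC mice (SD, n = 2) and 8.05% ± 3.47 in chow mice (SD, n = 3) and were not compared.

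Counts were summed per mouse over the cells of a type with at least 20 cells in every mouse, so that the mouse was the replicate. HC was compared with chow in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood test, two-sided, Benjamini-Hochberg adjusted p under 0.05), in beta, alpha, delta, macrophage and endothelial cells. A gene-by-gene test of whether the diet effect differed between macrophages and beta cells used the interaction of diet and cell type with the mouse as a block. Gene lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry. Shares of cells were compared with a two-sided exact permutation test over the 10 splits of the 5 mice, whose smallest p is 0.1. Intervals of shares are exact 95% binomial intervals and cover counting error only.

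The gene lists, the tests and the rule for naming genes were fixed before the data were examined. The rule took the largest changes past the threshold, 10 per direction in beta cells and 5 in other types, among genes with a mean log2 CPM of at least 4 whose HC mice both lay beyond all chow mice. Where fewer than 5 genes passed, it took the 5 of smallest p in each direction, to be given as not past the threshold. It also took 2 to 4 members of smallest p of each list described, the 5 smallest p of the interaction, and Ins1, Ins2, Gcg, Sst and Cd74 in all cases. Some genes that the rule takes are not described in the text.

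On data simulated from the sums with genes changed 2-fold or 4-fold, 71% of 2-fold and 95% of 4-fold changes were recovered in beta cells, 67.3% and 93.8% in alpha cells, and 57.7% and 95.8% in delta cells. Recovery was 28.7% and 88.4% in macrophages and 24.2% and 85.3% in endothelial cells, so most 2-fold changes are missed in these types. False calls were 8 of 174 in beta, 14 of 171 in alpha, 19 of 166 in delta, 16 of 127 in macrophage and 8 of 112 in endothelial cells. In beta cells 100 tested genes of each fold had been changed, where the real comparison called 1 gene. With so many changed genes the adjusted threshold is more lenient. Genes were also drawn independently of each other and without a difference between prefixes. Recovery in the real comparisons can therefore be lower.

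Alternatives were DESeq2 1.42.0, relative log expression scaling, no filter on low counts, prefix or age as a term, the title's grouping, a stricter cell filter (at most 5% mitochondrial UMIs, at least 1000 genes), no cell filter, called doublets kept, equal cell numbers per mouse, Leiden resolution 0.5, and leaving out each mouse. For the lists the estimated correlation was tried too. The interaction was fitted only with relative log expression scaling, no filter on low counts, the title's grouping, equal cell numbers and each mouse left out. Its ranges over alternatives cover these alone.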

Results

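Single-cell RNA sequencing was available for the islets of 5 NOD.SCID mice, 3 fed chow and 2 fed 20% HC, a diet whose protein is hydrolyzed casein. Chow mice 1, 2 and 3 were 8, 10 and 10 weeks old, and HC mice 1 and 2 were 7 and 9 weeks old. The libraries held 29959427 UMIs in 4452 barcodes (chow 1), 39624978 in 6087 (chow 2), 29796212 in 5522 (chow 3), 28722244 in 5231 (HC 1) and 29485548 in 5182 (HC 2). After filtering, 3651, 5122 and 4744 cells of the chow mice and 4819 and 4408 cells of the HC mice remained. Median UMIs per kept cell were 6673, 6958 and 5910 in chow mice and 5146 and 5639 in HC mice, and median detected genes were 1511, 1315 and 1184 against 1250 and 1357. The median mitochondrial share of a cell was 2.79%, 2.01% and 2.38% in chow mice against 3.61% and 2.62% in HC mice. The comparisons ask how the HC diet changes the cells of the islet in mice without T and B cells.

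Beta cells made up less of the islet suspensions of HC mice, and alpha cells more. Beta cells were 41.9% ± 1.99 of kept cells in HC mice (SD, n = 2) and 51.4% ± 2.59 in chow mice (SD, n = 3), and alpha cells were 23.4% ± 2.59 and 16.9% ± 1.13. For both types the 2 HC mice lay beyond all 3 chow mice, which in this design gives the smallest possible exact permutation p of 0.1. For beta cells this separation was lost with the stricter cell filter (48.4% ± 1.74 against 57.8% ± 9.20, exact permutation p = 0.3), at Leiden resolution 0.5 (36.3% ± 0.34 against 44.8% ± 11.7, 0.4) and by title (-5.38 points, 0.6). At resolution 0.5 a cluster led by Ins2 and Ins1 was left unnamed because acinar markers were also among its leading genes. It held 632, 102 and 41 cells of chow mice 1, 2 and 3 and 355 and 180 of HC mice 1 and 2. The loss of separation at that resolution can therefore come from the naming rule. Delta cells were 12.1% ± 0.369 against 11.4% ± 1.03 (exact p = 0.5). Macrophages were 2.44% ± 0.689 against 1.75% ± 0.438 (exact p = 0.3), and endothelial cells 4.56% ± 2.25 against 3.00% ± 1.16 (exact p = 0.5). Within the FUN libraries the beta share differed by -5.37 points (HC minus chow) and within the SKY libraries by -12.3 points; for alpha cells these differences were 9.59 and 4.04 points. The delta share differed by -0.136 and 1.02 points, the macrophage share by 0.39 and 1.08 points, and the endothelial share by -0.922 and 3.59 points. The endothelial difference was 1.55 points with all 5 mice, -0.037 without HC mouse 2, 3.14 without HC mouse 1 and 0.895 without chow mouse 3. The macrophage difference was 0.685 points, 0.197 without HC mouse 2 and 1.17 without HC mouse 1. The delta difference was 0.72 points, 1.28 without chow mouse 1, 0.459 without HC mouse 1 and 0.258 without chow mouse 2. Islets were picked by hand, which can set these shares.

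**Figure D1:**
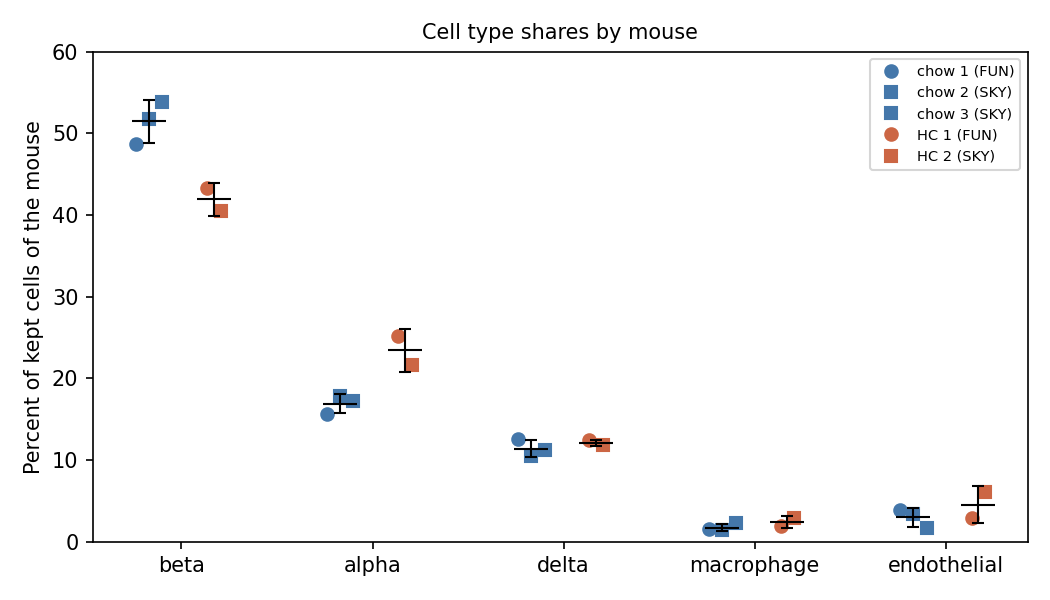
Share of kept cells (percent, vertical axis) of each cell type in each mouse, circles for FUN and squares for SKY libraries, with the mean and SD of the 3 chow and 2 HC mice. Beta cells averaged 41.9% in HC against 51.4% in chow mice, and alpha cells 23.4% against 16.9%.

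In beta cells, the list of immediate-early and heat-shock genes was lower in HC mice, while those of the amino acid response, the unfolded protein response and the mitochondrial genome were slightly higher. None of these 4 calls held with an estimated correlation (adjusted p = 0.834, 0.881, 0.834 and 0.834), and 0 of their members passed over all genes. Insulin transcripts themselves differed little, with log2 HC over chow of -0.09 ± 0.171 (SE) for Ins1 and -0.12 ± 0.177 for Ins2 (adjusted p = 0.996 and 0.991, edgeR). The dissociation-response list, which holds immediate-early and heat-shock genes, fell (median log2 -0.45, 5 of 25 members above 0, camera adjusted p = 7.75e-16). Its adjusted p was 0.834 with an estimated correlation. Of its members 0 passed the test over all genes, and 9 were lower when adjusted over the list alone. Junb, an AP-1 transcription factor gene, had log2 -0.62 ± 0.117 and Hspa1b, which encodes an HSP70 chaperone, -0.71 ± 0.136 (adjusted p = 0.131 for each). With prefix as a term Junb passed (adjusted p = 0.00813). The list median was -0.68 within FUN and -0.35 within SKY libraries.

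The amino acid response list rose in beta cells by a median log2 of 0.17 (20 of 24 members above 0, camera adjusted p = 0.000116; adjusted p = 0.881 with an estimated correlation; 0.21 within FUN and 0.14 within SKY). The unfolded protein response rose by 0.15 (24 of 28, adjusted p = 0.000226; 0.11 within FUN and 0.17 within SKY) and the mitochondrially encoded transcripts by 0.27 (10 of 13, adjusted p = 0.00444; 0.26 within FUN and 0.20 within SKY). These became adjusted p = 0.881, 0.834 and 0.834 with an estimated correlation. Of these 3 lists 0 members passed over all genes, and adjusted over the list alone 2 amino acid response genes were higher. Nupr1, a stress-induced chromatin regulator, had log2 1.09 ± 0.173 (adjusted p = 0.118) and Aldh1l2, a mitochondrial folate enzyme, 0.72 ± 0.188 (0.564). Ddit3, the stress transcription factor CHOP, had 0.40 ± 0.112 (0.711), Sel1l 0.33 ± 0.119 (0.937), mt-Nd3 0.35 ± 0.105 (0.798) and mt-Nd2 0.43 ± 0.146 (0.937). The amino acid call was lost without HC mouse 1 (median 0.08, adjusted p = 0.0883), and its median was 0.28 without chow mouse 1, 0.09 without chow mouse 2 and 0.33 without HC mouse 2. The unfolded protein response call was lost without HC mouse 2 (median 0.04, adjusted p = 0.455). The mitochondrial call was lost without chow mouse 2 (median 0.17, 0.0617), chow mouse 3 (0.28, 0.0573) and HC mouse 2 (0.39, 0.0728), and its median was 0.09 without HC mouse 1. With age as a term the amino acid median was 0.045 and the mitochondrial one 0.065, and with prefix as a term the amino acid median was 0.11 and Nupr1 passed (adjusted p = 0.00813).

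Over all genes, 1 of 11865 passed in beta cells. C1rl (ENSMUSG00000038527, GRCm38 chromosome 6, 124493113 to 124510643), a complement C1r-like protease gene, rose by log2 3.34 ± 0.354 (SE, adjusted p = 0.00277, edgeR's quasi-likelihood test). Its level was low, 3.15 ± 1.01 CPM in HC (SD, n = 2) and 0.307 ± 0.124 in chow mice (SD, n = 3), and both HC mice lay above all chow mice. HC mice lay beyond all chow mice, above or below, for 21.0% of genes tested in beta cells (20.0% by chance). C1rl was 2.85 within FUN and 2.91 within SKY libraries. The call was lost without HC mouse 1 (adjusted p = 0.0712) and without chow mouse 3 (0.216), and over all alternatives the adjusted p ran from 5.48e-18 to 0.627. The other genes of smallest p did not pass: Pcp4, Xlr3a and S100a10 had log2 0.91, 1.09 and 0.69 (adjusted p = 0.0779 for each), and Rasd1, Cryba2 and C2cd4a had -0.63, -0.64 and -0.76 (0.0779, 0.11 and 0.118). With prefix as a term Pcp4, Xlr3a, S100a10, Rasd1 and Cryba2 did pass (adjusted p = 0.0126, 0.0234, 0.0184, 0.043 and 0.00656), among 15 genes. The count was 4 without chow mouse 1, 6 without HC mouse 2 and 0 without HC mouse 1 or chow mouse 3, where 607 and 663 genes had an unadjusted p under 0.05. DESeq2 called 13 genes and gave C1rl no adjusted p.

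In alpha cells of HC mice, Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, was less than 50% of its chow level. Cdkn1a (ENSMUSG00000023067, GRCm38 chromosome 17, 29090976 to 29100727) was 36.3 ± 2.49 CPM in HC (SD, n = 2) and 79.9 ± 14.5 in chow mice (SD, n = 3). It fell by 1.13 on the log2 scale (SE 0.152, adjusted p = 0.0185, edgeR) and was the 1 gene of 10809 that passed. It was -1.32 within FUN and -1.04 within SKY libraries. The adjusted p was 0.068 without chow mouse 2 and ran from 4.66e-11 to 0.775 over all alternatives, and DESeq2 gave 0.00067. Gcg, the glucagon gene, had log2 -0.09 ± 0.134 (adjusted p = 0.91).

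The senescence and p53 list, which includes Cdkn1a, fell in alpha cells (median log2 -0.16, 5 of 17 members above 0, camera adjusted p = 0.00069; -0.15 within FUN, -0.14 within SKY), with 1 member lower over all genes and 2 lower when adjusted over the list alone. Its adjusted p was 0.669 with an estimated correlation, and 0.125 without HC mouse 2. Phlda3 had log2 -1.01 ± 0.177 (adjusted p = 0.137), Bax, a pro-apoptotic gene, -0.34 ± 0.122 (0.696) and Ccng1 -0.41 ± 0.181 (0.704). Ly6e had -0.72 ± 0.124 (0.137), Serpine2 -0.90 and Spc25 -0.71 (0.145 for each). Phlda3 and Ly6e passed with prefix as a term (adjusted p = 0.0294 and 0.0189). Sgms1, 2310001H17Rik, Rasgrf2, Dzank1 and Lncpint had the smallest p among higher genes, with log2 from 0.73 to 1.28 and adjusted p from 0.145 to 0.245. The number of genes called in alpha cells was 4 without chow mouse 1, 4 without HC mouse 1, 0 without chow mouse 2 (488 at an unadjusted p under 0.05) and 18 without HC mouse 2.

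In the alpha cell sums of HC mice the beta marker list fell (median -0.70, 0 of 10 above 0, adjusted p = 4.05e-10), as did the beta identity list (-0.27, 8 of 27, 0.000263) and the islet autoantigens (-0.28, 2 of 10, 0.0407). These 3 lists had adjusted p = 0.669 with an estimated correlation. Mafa had log2 -0.97 ± 0.203 (adjusted p = 0.266, and 0.0294 with prefix as a term), G6pc2 -0.82 ± 0.204 (0.496) and Chga -0.51 ± 0.144 (0.624). Ins1 and Ins2 together took 9.38% ± 3.15 of alpha cell UMIs in chow mice (SD, n = 3) and 6.30% ± 1.41 in HC mice (SD, n = 2). Within FUN libraries these list medians were 0.00, 0.09 and 0.06, and within SKY libraries -1.02, -0.44 and -0.77, so the 3 falls did not hold in FUN. Without HC mouse 2 the identity and autoantigen calls were lost (adjusted p = 0.746 and 0.504), and without chow mouse 2 the autoantigen call (0.069). Adjusted over the list alone 2 members were lower in each of the 3 lists, and 0 passed over all genes. The autoantigen call was also lost with prefix as a term (0.0761), the stricter cell filter (0.313) and equal cells (0.094).

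Mitochondrially encoded transcripts rose in alpha cells (median 0.34, 11 of 13 above 0, adjusted p = 0.000263; adjusted p = 0.669 with an estimated correlation; 0.44 within FUN, 0.20 within SKY), with mt-Nd3 at 0.48 ± 0.145 (adjusted p = 0.661) and mt-Nd2 at 0.52 ± 0.169 (0.661). This median was 0.16 without HC mouse 1 and 0.18 with age as a term. Nuclear genes of the respiratory chain fell (-0.12, 9 of 66 above 0, adjusted p = 0.00168, and 0.669 with an estimated correlation; -0.12 within FUN, -0.04 within SKY), with Ndufb8 at -0.38 ± 0.114 and Cox5a at -0.40 ± 0.144 (adjusted p = 0.661 and 0.696); without HC mouse 1 the list turned up (0.464), and without chow mouse 2 the call was lost (0.0932). The dissociation list fell (-0.18, 9 of 26 above 0, adjusted p = 0.00166, and 0.669 with an estimated correlation; -0.38 within FUN, -0.06 within SKY), with Socs3 at -1.15 ± 0.294 (0.624, and 0.0227 with prefix as a term) and Gadd45g at -0.72 ± 0.151 (0.217). That call was lost without chow mouse 1 (0.0615), HC mouse 1 (0.0667) and chow mouse 2 (median -0.12, 0.0792), and its median was -0.30 without chow mouse 3 or HC mouse 2. The amino acid response rose (0.19, 16 of 20 above 0, adjusted p = 0.0375, and 0.669 with an estimated correlation; 0.29 within FUN, 0.06 within SKY), with Slc38a2, an amino acid transporter gene, at 0.34 ± 0.128 (0.696) and Cebpb at -0.29 ± 0.141 (0.704). It was lost without HC mouse 1 (median 0.10, 0.898), chow mouse 1 (0.129) and chow mouse 2 (0.107), with prefix as a term (0.075) and with the stricter cell filter (0.0672), and its median was 0.42 without HC mouse 2. Adjusted over the list alone, 1 dissociation gene was higher and 4 were lower, and 0 members of the other 3 lists passed.

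In delta cells no single gene passed, and the list of heat-shock and immediate-early genes was lower in HC mice (camera; adjusted p = 0.943 with an estimated correlation). edgeR called 0 of 10277 genes, with 315 at an unadjusted p under 0.05, and DESeq2 called 0. The count was 2 without chow mouse 1 and 3 without HC mouse 2. The dissociation list fell (median -0.21, 1 of 24 above 0, camera adjusted p = 4.6e-12; -0.34 within FUN, -0.28 within SKY), with 8 members lower when adjusted over the list alone. Its median was -0.37 without HC mouse 1, -0.10 without chow mouse 2, -0.38 without chow mouse 3 and -0.34 with age as a term. The HSP70 genes Hspa1b and Hspa1a had log2 -1.02 ± 0.192 (adjusted p = 0.414) and -0.95 ± 0.182 (0.427), and Rnf181, Junb and Timp1 had -1.04, -0.65 and -0.83 (0.427, 0.999 and 0.999). With prefix as a term Hspa1b, Hspa1a and Junb passed (adjusted p = 0.024, 0.000569 and 0.0365). Xlr3a, Dctn5, Khdc4, Tcp11l2 and Gm20342 had log2 from 0.69 to 1.31 (0.999 for each). Sst, the somatostatin gene, had 0.02 ± 0.215 (adjusted p = 0.999).

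Mitochondrially encoded transcripts rose in delta cells (median 0.25, 12 of 13 above 0, adjusted p = 0.00261; adjusted p = 0.943 with an estimated correlation; 0.21 within FUN, 0.20 within SKY), with mt-Nd3 at 0.41 and mt-Nd2 at 0.48 (adjusted p = 0.999 for each). This call was lost without chow mouse 2 (0.0825) and chow mouse 3 (0.112), and its median was 0.39 without chow mouse 1, 0.08 without HC mouse 1, 0.46 without HC mouse 2 and 0.04 with age as a term. Acinar transcripts rose too (0.16, 14 of 19 above 0, adjusted p = 0.0431, and 0.943 with an estimated correlation), but were -0.73 within FUN and 1.48 within SKY libraries. That call was lost without HC mouse 1 (0.0733), chow mouse 2 (0.473), chow mouse 3 (0.669) and HC mouse 2 (0.23), with the stricter cell filter (0.333) and with equal cells (0.059). Cpa1 and Ctrc, genes of digestive enzymes, had log2 0.71 ± 0.55 and 0.68 ± 0.766 (adjusted p = 0.999 for each). Both lists had 0 members past the test, over all genes or adjusted over the list alone.

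In the summed counts of islet macrophages, insulin transcripts were lower in HC mice, and the lists of interferon-stimulated and lysosomal genes were higher. The 2 list calls did not hold with an estimated correlation (adjusted p = 0.627 and 0.814), and 0 of their members passed over all genes. Ins1 (ENSMUSG00000035804, GRCm38 chromosome 19, 52264297 to 52265476) fell by 0.88 on the log2 scale (SE 0.143) and Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381) by 0.94 (SE 0.154), each with adjusted p = 0.0266 (edgeR), the 2 of 2502 genes that passed. Ins1 and Ins2 together were 13.7% ± 0.604 of macrophage UMIs in HC mice (SD, n = 2) and 24.0% ± 2.80 in chow mice (SD, n = 3). The median macrophage held far less, 0.585% ± 0.005 against 1.57% ± 0.879 (exact permutation p = 0.2), but medians were lower in the other types too: 0.502% ± 0.238 against 1.42% ± 0.814 in endothelial (0.3), 0.396% ± 0.036 against 1.47% ± 0.772 in stromal (0.2), 0.438% ± 0.021 against 0.939% ± 0.393 in delta (0.2) and 0.312% ± 0.039 against 0.627% ± 0.289 in alpha cells (0.3). Cells with at least 20% insulin UMIs were 8.52% ± 0.014 of macrophages in HC and 12.6% ± 2.04 in chow mice (exact permutation p = 0.2). They were 8 of 94 and 11 of 129 macrophages in HC mice 1 and 2. In chow mice 1, 2 and 3 they were 8 of 57, 10 of 74 and 11 of 107. Exact binomial intervals were 3.75% to 16.08% and 4.33% to 14.75% in the HC mice, and overlapped those of all chow mice. The SD of 0.014 therefore leaves out most of the counting error. Most of the summed insulin lay in these 8 to 11 cells per mouse, on which the 2 calls mainly rest. The other macrophages summed to 0.878% ± 0.093 in HC and 1.46% ± 0.631 in chow mice (exact permutation p = 0.3). Within FUN and SKY libraries Ins1 was -1.07 and -0.74, and Ins2 -1.28 and -0.70.

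The 2 insulin calls were lost without chow mouse 1 (adjusted p = 0.595), chow mouse 2 (0.453) or chow mouse 3 (0.642), and without the cells of highest doublet scores (log2 -0.52 for Ins1 and -0.56 for Ins2, adjusted p = 1 for each), with equal cells (1), with no cell filter (0.37) and with DESeq2 (0.133). Ins2 also lost its call with prefix or age as a term (0.19 and 0.155), where Ins1 kept it (0.000927 and 0.00333). Over all alternatives the adjusted p of Ins1 ran from 0.000909 to 1 and that of Ins2 from 1.07e-05 to 1; DESeq2 called 0 genes, with 32 at an unadjusted p under 0.05. The number of calls was 0 without any 1 of the chow mice (91, 74 and 114 genes at an unadjusted p under 0.05), 21 without HC mouse 1 and 4 without HC mouse 2. Lists of beta cell transcripts, which include Ins1 and Ins2, fell: the beta marker list (median -0.88, 0 of 9 above 0, adjusted p = 7.21e-09), the identity list (-0.62, 4 of 16, 2.95e-06) and the autoantigens (-0.64, 1 of 7, 0.000191). All 3 had adjusted p = 0.627 with an estimated correlation. Their medians were -1.07, -0.83 and -0.93 within FUN and -0.70, -0.51 and -0.56 within SKY libraries. Apart from Ins1 and Ins2, 1 member, Chga (log2 -0.64 ± 0.205), was lower when adjusted over the list alone. Without chow mouse 1 the identity list had adjusted p = 0.0555 and the autoantigens 0.0992; the autoantigens had 0.0784 without HC mouse 1 and 0.0849 without chow mouse 2. Ucn3, Slc2a2, Nkx6-1 and G6pc2 had log2 -1.24, -0.78, -1.61 and -0.51 (adjusted p = 0.999 for each). Cul3 had -1.63 (0.999).

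Interferon-stimulated genes rose in macrophages (median 0.31, 13 of 13 members above 0, camera adjusted p = 1.24e-05; 0.64 within FUN, 0.20 within SKY). The list had adjusted p = 0.627 with an estimated correlation, 2 members higher when adjusted over the list alone and 0 over all genes. Isg15, a ubiquitin-like interferon effector, was 107.2 ± 2.57 CPM in HC (SD, n = 2) and 38.8 ± 12.1 in chow mice (SD, n = 3), a log2 difference of 1.40 ± 0.367 (adjusted p = 0.871, edgeR). Rtp4 had 1.35 ± 0.366 (adjusted p = 0.91). The call held without each mouse in turn, and its median was 0.61 without chow mouse 3, 0.59 without HC mouse 2 and 0.49 with age as a term. Lysosomal and lipid-handling genes rose (0.33, 23 of 25, adjusted p = 0.000215, and 0.814 with an estimated correlation; 0.26 within FUN, 0.49 within SKY), with Lpl, lipoprotein lipase, at 1.02 ± 0.371 and Psap, a lysosomal cofactor, at 0.46 ± 0.189 (0.999 for each). That call was lost without chow mouse 1 (0.0555) and HC mouse 2 (0.445). MHC class I genes rose (0.29, 13 of 15, adjusted p = 0.00683, and 0.814 with an estimated correlation; 0.60 within FUN, 0.06 within SKY), with Psme2 at 0.50 ± 0.292 and Psmb8 at 0.32 ± 0.258 (0.999 for each); that call was lost without chow mouse 1 (0.133), HC mouse 1 (0.799) and chow mouse 2 (0.0584). Both lists had 0 members past the test. Cd74, the MHC class II invariant chain, had 0.09 ± 0.368 (0.999).

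The dissociation list fell in macrophages (-0.31, 3 of 23 above 0, adjusted p = 0.002; -0.31 within FUN, -0.19 within SKY), with Gadd45b at -0.90 ± 0.48 and Dnajb1 at -0.83 ± 0.465 (0.999 for each); its median was -0.16 with age as a term, and it was lost without HC mouse 1 (median -0.17, 0.0944) and had adjusted p = 0.627 with an estimated correlation. Transcripts of other islet cells moved as well. Delta and PP markers rose (0.54, 4 of 5, adjusted p = 0.00238, and 0.627 with an estimated correlation; 3.41 within FUN, 0.64 within SKY), with Sst at 2.11 ± 1.51 and Rbp4 at 1.35 ± 0.319 (0.999 and 0.849), where Rbp4 passed with prefix as a term (adjusted p = 0.0403). Acinar markers rose (0.51, 9 of 10, adjusted p = 0.00404, and 0.822 with an estimated correlation; -1.24 within FUN, 2.35 within SKY), with Try5 at 1.17 ± 0.698 and Cpa1 at 1.42 ± 1.08 (0.999 for each). Adjusted over the list alone, 1 delta and PP marker was higher and 0 acinar or dissociation genes passed; over all genes 0 of the 3 lists' members did. The delta and PP call was lost without chow mouse 1 (0.21) and HC mouse 1 (0.0536), and the acinar call without chow mouse 2 (0.379), chow mouse 3 (0.647) and HC mouse 2 (0.881). Dbpht2 and 9930111J21Rik2 had log2 1.65 and 1.33 (0.871 and 0.999).

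In endothelial cells of HC mice, interferon-stimulated genes were higher across the whole list: 32 of 32 members lay above 0, with a median log2 of 0.75. The list rose in camera (adjusted p = 1.21e-32), with 1 member higher over all genes and 13 when adjusted over the list alone. It had adjusted p = 0.399 with an estimated correlation. The median was 0.69 within FUN and 0.56 within SKY libraries. The call held without each mouse in turn (adjusted p from 1.65e-35 to 2.19e-19) and under the title's grouping (1.02e-14, median 0.44). The mean log2 level of the list per mouse was 7.68 and 7.43 in HC mice and 6.75, 6.59 and 6.86 in chow mice. In beta cells 13 of 22 members lay above 0 (median 0.07, mean 0.03, camera down, adjusted p = 0.944), in alpha cells 10 of 19 (median 0.00, 0.432) and in delta cells 11 of 20 (0.03, 0.774); the difference between cell types was not tested for lists.

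Ifit3 (ENSMUSG00000074896, GRCm38 chromosome 19, 34583531 to 34588731), an antiviral interferon-induced gene, was 119.3 ± 9.23 CPM in HC (SD, n = 2) and 27.8 ± 1.66 in chow mice (SD, n = 3). It rose by log2 2.10 ± 0.34 (SE, adjusted p = 0.0158, edgeR; 1.84 within FUN, 1.87 within SKY). Irf7, the transcription factor that drives interferon production, had 1.22 ± 0.259 (adjusted p = 0.186), and Ifit1 1.58 ± 0.361 (0.277); with prefix as a term both passed (adjusted p = 0.0464 for each). Gm4951 had 2.48 ± 0.594 (0.334). Car4 (ENSMUSG00000000805, chromosome 11, 84957786 to 84966044), a membrane-bound carbonic anhydrase of capillary endothelium, was 175.7 ± 25.0 against 475.9 ± 152.6 CPM and fell by 1.46 on the log2 scale (SE 0.242, adjusted p = 0.0192; -1.71 within FUN, -1.25 within SKY).

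These 2 genes were the calls among 5177. Both HC mice lay beyond all chow mice for each, as for 16.5% of tested genes (20.0% by chance). Both had adjusted p = 0.0515 without chow mouse 1, 0.422 without chow mouse 2 and 0.0792 without chow mouse 3; the range over all alternatives was 9.63e-05 to 0.999 for Ifit3 and 5.68e-06 to 1 for Car4. Both calls were lost with equal cells (0.947) and at Leiden resolution 0.5 (0.336 and 1), and Ifit3 with no cell filter (0.242). DESeq2 called 0 genes, with 37 at an unadjusted p under 0.05, and the count was 0 without chow mouse 2 or chow mouse 3 (119 and 169 genes at an unadjusted p under 0.05), 9 without HC mouse 1 and 32 without HC mouse 2. The dissociation list fell (median -0.30, 3 of 25 above 0, adjusted p = 1.21e-05, and 0.819 with an estimated correlation; -0.53 within FUN, -0.04 within SKY), with 0 members past the test over all genes and 2 lower when adjusted over the list alone. Ier5 and Ier3, immediate-early genes, had log2 -0.84 ± 0.217 (adjusted p = 0.53) and -0.81 ± 0.244 (1). Alpha cell markers fell (-1.01, 0 of 5 above 0, adjusted p = 0.0246, and 0.822 with an estimated correlation; -0.14 within FUN, -1.33 within SKY), with 0 members past the test and Peg3 at -1.01 ± 0.365 (adjusted p = 1). The dissociation median was -0.19 without chow mouse 1, and the alpha marker call was lost without HC mouse 1 (0.182) and chow mouse 3 (0.28) and with prefix as a term (0.0589). Plin3 and Slc39a7 had -1.50 and -1.14 (1 for each).

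**Figure D2:**
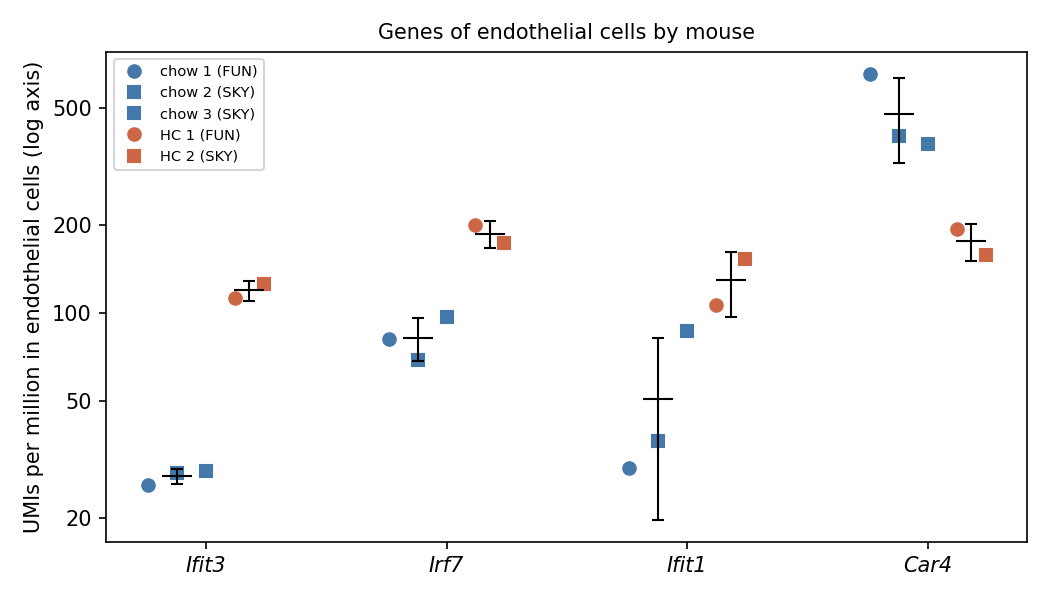
CPM (log axis) of 4 genes in the endothelial cells of each mouse, circles for FUN and squares for SKY libraries, with the mean and SD of the 3 chow and 2 HC mice. Ifit3 averaged 119.3 in HC against 27.8 in chow mice, and Car4 175.7 against 475.9.

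**Figure D3:**
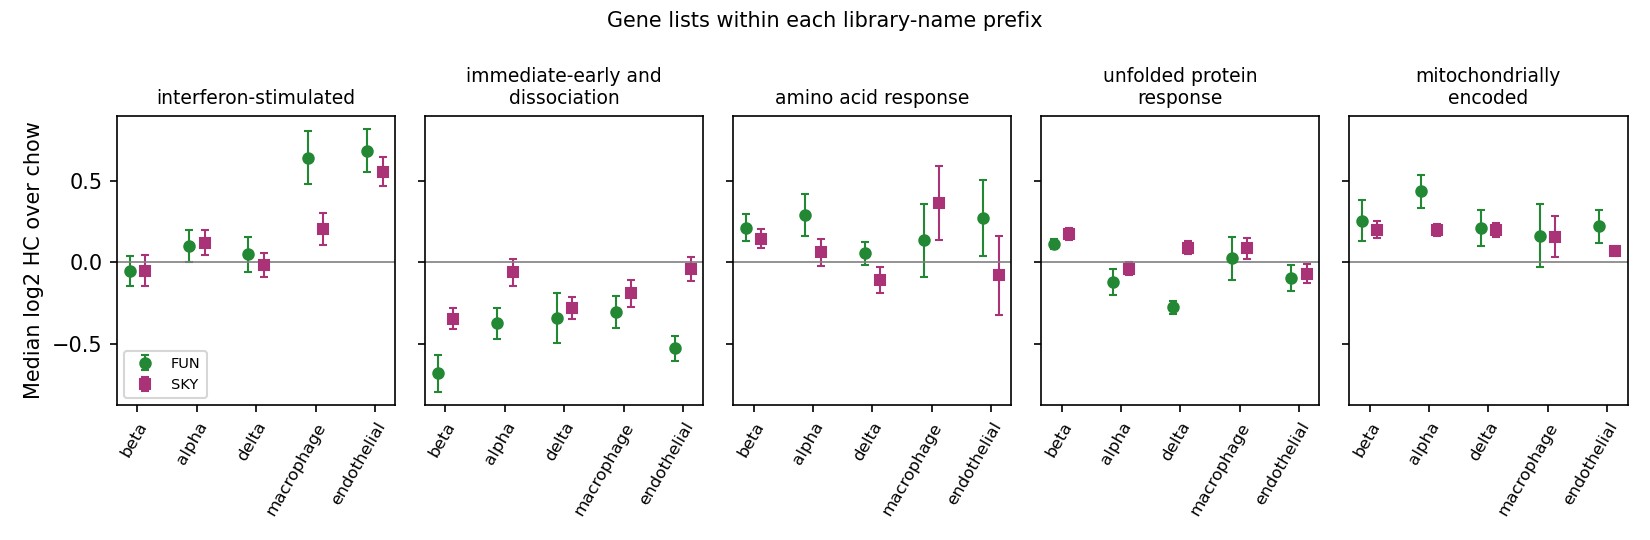
Median log2 HC over chow of 5 gene lists within FUN (HC 1 against chow 1) and within SKY libraries (HC 2 against chow 2 and 3) in 5 cell types, with error bars of 1 SE over the list members. The interferon median in endothelial cells was 0.69 within FUN and 0.56 within SKY.

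The diet effect was compared directly between macrophages and beta cells. In the summed counts it differed for 6 of 12284 genes (edgeR, interaction of diet and cell type), none of them a macrophage marker. The insulin gene Ins1 fell more in the macrophage sums, by -0.74 ± 0.114 relative to beta cells (adjusted p = 0.000205). Rbp4, a retinol carrier gene expressed in delta cells, differed the other way (1.34 ± 0.247, adjusted p = 0.000169). The hemoglobin genes Hba-a1, Hbb-bt and Hbb-bs made up the rest of the 5 smallest p (1.66e-48, 1.33e-30 and 2.62e-28). Hbb-bs was at 1481.6 CPM in the macrophages of HC mouse 2, 0 in those of HC mouse 1, and 0, 0 and 10.9 in those of chow mice 1, 2 and 3. In beta cells it was 29.1 and 36.7 CPM in chow mice 2 and 3 and at most 0.44 in the other mice, so both cell types enter the difference. The sixth gene, Shisal2b, was chosen after its values were seen (2.90 ± 0.643, 0.0139). It was among the leading genes of the delta cluster. Of the markers fixed in advance, Ins1 stood for beta, Rbp4 for delta and the hemoglobin genes for erythroid cells. The 6 are thus transcripts of cell types other than macrophages, and a differing response of macrophage genes is not shown. Ins1 had adjusted p = 0.0589 without chow mouse 1 and 1 without HC mouse 1, chow mouse 3 or HC mouse 2, with a range over all alternatives of 3.1e-11 to 1. It also lost its call with relative log expression scaling (0.712) and, as Rbp4 and Shisal2b did, with equal cells (0.27, 1 and 1). Rbp4 had 0.235 without chow mouse 1 and 1 without HC mouse 2 (range 1.16e-06 to 1), and Shisal2b 0.148, 0.0547, 0.489 and 0.724 without chow mouse 1, HC mouse 1, chow mouse 2 and HC mouse 2 (range 0.0019 to 1). Without HC mouse 2 each hemoglobin gene had adjusted p = 1 and the count was 0, with 389 genes at an unadjusted p under 0.05; it was 11 without HC mouse 1, 10 without chow mouse 2, 14 without chow mouse 3 and 4 without chow mouse 1.

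Grouping HC mouse 2 by its title, as another chow mouse, ended the calls of C1rl in beta cells (adjusted p = 0.627), Cdkn1a in alpha cells (0.775), Ins1 and Ins2 in macrophages (0.956 for each), and Ifit3 and Car4 in endothelial cells (0.96 and 0.949). It also ended the list calls of the unfolded protein response and mitochondrial transcripts in beta cells (adjusted p = 0.825 and 0.0637), of p53 genes, beta markers, beta identity and autoantigens in alpha cells (0.922, 0.753, 0.26 and 0.997), of acinar markers in delta cells (0.344) and of alpha markers in endothelial cells (0.0847). In macrophages it ended those of beta markers, beta identity, autoantigens, delta and PP markers, acinar markers and lysosomal genes (0.161, 0.136, 0.28, 0.28, 0.959 and 0.959). The interferon lists of macrophages and endothelial cells and the dissociation lists of all 5 types stayed past the threshold, but sizes moved. By the diet label none of these calls held with an estimated correlation. Camera then gave adjusted p = 0.627 and 0.399 for the interferon lists. For dissociation it gave 0.834, 0.669, 0.943, 0.627 and 0.819 in beta, alpha, delta, macrophage and endothelial cells. The beta dissociation median was -0.22, where the diet label gave -0.45, the macrophage interferon median 0.58 (17 of 22 members above 0) and the endothelial one 0.44 (31 of 35).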

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

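The tests of free RNA in the macrophage sum and of the smaller beta cell share were chosen after the results were seen.

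Ins1 was singled out because its diet effect was tested as different between macrophages and beta cells, by -0.74 on the log2 scale (adjusted p = 0.000205).

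Free RNA from beta cells may explain the level in the median macrophage: its insulin percentage was 0.869 to 1.59 times the higher of the endothelial and stromal medians of the same mouse. As a source of the whole sum over macrophages it is argued against by the spread of insulin over cells. Between 8.51% and 14.04% of macrophages held 20% insulin or more, and the rest summed to 0.812% to 2.11%. The whole sum was at least 5.99 times the endothelial one in each mouse. That ratio cannot decide, because cluster 15, whose leading genes were endothelial, was left unnamed for its hormone level. Its cells held 12.2% Ins1 and 31.1% Ins2. At Leiden resolution 0.5 the endothelial cluster held 5.42% and 13.8%, and the macrophage cluster 4.23% and 10.8%. Stromal sums, where 6.25% to 27.6% of cells were such cells, held 19.2% to 35.3% insulin, so a high sum is not particular to macrophages. A smaller share of beta cells in HC mice would lower Ins1 by about as much as the share, but Ins1 lay -0.58 and Ins2 -0.65 below the log2 ratio of the shares (-0.29). Macrophages at 20% insulin or more had median UMIs of 12880, 6748, 6770, 7890 and 8633 (chow 1, HC 1, chow 2, chow 3, HC 2) against 1813, 1442, 1310, 1662 and 1716 in the others, and stromal cells of that kind 12418, 7226, 7541, 8378 and 13687 against 1345, 1432, 1527, 1810 and 1981. Totals that high favour 2 cells in 1 droplet as the source of insulin in those cells. Without the highest doublet scores Ins1 shrank to -0.52 and Ins2 to -0.56. The diet difference in summed insulin was -10.3 points with all macrophages (exact permutation p = 0.1). Without those at 20% insulin or more it was -0.581 points, and HC and chow mice overlapped (exact permutation p = 0.3). Leaving out the cells richest in insulin must shrink a difference in points, so this does not test them as its source. The measure set beforehand was the log2 difference, -0.80 with them and -0.64 (SE 0.394) without them. Given that SE, it cannot be told apart from the threshold set for it, -0.402, so the test cannot decide. The ratio without them covers a remainder of 0.812% to 2.11% insulin, and medians were lower in the other types too, so it does not bear on the whole sum. With age as a term Ins1 was -0.91 and Ins2 -1.01 (adjusted p = 0.00333 and 0.155, edgeR). That fit cannot separate age from diet. Its age slope comes from FUN against SKY, and within each prefix the HC mouse was younger than its chow mice. Age therefore stays open, and uptake of insulin granules was not tested.

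The other genes singled out by the same test of the difference were Hba-a1 (10.07, adjusted p = 1.66e-48), Hbb-bt (17.58, 1.33e-30), Hbb-bs (13.49, 2.62e-28), Rbp4 (1.34, 0.000169) and Shisal2b (2.90, 0.0139). Hba-a1, Hbb-bt and Hbb-bs were at 412.1, 214.9 and 1481.6 CPM in the macrophages of HC mouse 2 and at 0 in those of chow mice 1 and 2 and HC mouse 1, so these fitted differences give no bound on a fold. In the macrophages of chow mouse 3 they were at 39.85, 0 and 10.87 CPM. Beta cells enter the difference too: Hba-a1 was at 10.75 and 11.72, Hbb-bt at 9.03 and 6.04 and Hbb-bs at 29.12 and 36.71 CPM in those of chow mice 2 and 3, and at most 0.44 in those of the other mice. Without HC mouse 2 they were -2.45, 5.54 and -0.46, with adjusted p = 1 for each. Hba-a1 was 19.10, Hbb-bs 20.56 and Shisal2b 11.06 without chow mouse 3, and Rbp4 was 0.93 without HC mouse 2 (adjusted p = 1) and 0.97 without chow mouse 1 (0.235). Shisal2b had adjusted p = 0.148, 0.0547, 0.489 and 0.724 without chow mouse 1, HC mouse 1, chow mouse 2 and HC mouse 2.

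Cells of cluster 8, whose leading genes include both Gcg and Sst, entered no comparison. Their median doublet score was 0.164, against 0.04 in alpha and 0.028 in delta cells. Median UMIs were 6262 against 3935 and 2532, and median genes 1934 against 1120 and 1110. They may be droplets with an alpha and a delta cell, which was not tested. They were 2.62% of the cells of HC mouse 1 (126 of 4819, 95% interval 2.18% to 3.11%), 0.703% of those of HC mouse 2, and 1.51%, 1.64% and 0.885% of those of chow mice 1, 2 and 3.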

How the results depend on the processing

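Removing the highest doublet scores was chosen after the data were seen. Of 200 values that answer a comparison, 123 were held to be the same, 74 moved and 3 reversed. A count was the same when equal to the main one or within 1.5 times of it. A share difference was the same when it kept its sign, whatever its size. There were 1564 values of 98 results for genes under the naming rule. Of these, 1388 kept direction and side of the threshold, 57 lost the threshold, 93 gained it and 26 reversed. Counts of called genes, in the order beta, alpha, delta, macrophage and endothelial cells where 5 are given, were as follows. No filter on low counts gave 49, 52, 4, 6 and 10, and age as a term 11, 4, 9, 4 and 11. Prefix as a term gave 15 in beta, 6 in alpha, 4 in delta and 6 in endothelial cells. The title's grouping gave 2, 20, 1, 0 and 17. DESeq2 gave 13 in beta, 3 in alpha, 0 in macrophage and 0 in endothelial cells. The stricter cell filter gave 3 in beta cells; it was not possible in macrophages, endothelial cells and the interaction, where the fewest cells of a mouse were 16. Resolution 0.5 gave 6 in beta and 0 in endothelial cells, no cell filter 0 in macrophages and 1 in endothelial cells, equal cells 0 in both, and removal of the highest doublet scores 3 in alpha cells and 0 in macrophages. Leaving out 1 mouse gave 0 to 6, 0 to 18, 0 to 3, 0 to 21 and 0 to 32, and for the interaction 0 to 14; the title's grouping gave 0 there. A group left with 1 mouse was assumed to vary like the other group. An estimated correlation left 0 lists in each of the 5 types. List counts were 5 in alpha, 5 in delta and 7 in endothelial cells by title, 5 in delta cells with prefix and 5 in endothelial cells with equal cells; leaving out 1 mouse gave 3 to 8, 4 to 11, 1 to 5, 6 to 9 and 3 to 13. The share difference reversed by title in macrophages (-0.096 points) and endothelial cells (-0.823), and in endothelial cells without HC mouse 2 (-0.037 to 3.14 over the mice left out). Named genes reversed by title were G6pc2 (0.30), Lpl (-0.48) and Try5 (-0.87) in macrophages, Sst in delta cells (-0.35), and Hba-a1 (-5.78), Hbb-bt (-6.36) and Hbb-bs (-6.06) in the interaction. With age as a term these were Ins1 (0.21) and Ins2 (0.18) in beta cells, Cpa1 (-0.056) and Ctrc (-0.27) in delta cells and Cd74 in macrophages (-0.44). Sst was -0.001 with the stricter filter, Psmb8 -0.046 at resolution 0.5, Cd74 -0.059 with prefix, and G6pc2 0.022 without the highest doublet scores. Leaving out 1 mouse gave -0.33 to 0.11 for Ins1 and -0.38 to 0.10 for Ins2 (reversed without HC mouse 1), -0.28 to 0.27 for Sst (reversed without chow mouse 1, chow mouse 2 or HC mouse 2) and -0.39 to 0.46 for Cd74 (reversed without HC mouse 1 or chow mouse 3). It gave -1.10 to 0.027 for G6pc2, -2.45 to 19.10 for Hba-a1 and -0.46 to 20.56 for Hbb-bs (reversed without HC mouse 2). Fewer mice or cells enter some settings by construction; otherwise the cause was not tested. Macrophages and endothelial cells, with 461 and 812 cells, had the lowest recovery and the highest variation between mice (23.5% and 18.7%, against 10.6% to 13.4%), and these were not separated.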

Other observations

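The comparison of FUN with SKY libraries, and the tests of prefix and of macrophage RNA for the interferon genes and of age and of transcripts under 500 nt for the prefix, were chosen after results were seen.

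Acinar transcripts were higher on average in the FUN libraries (chow mouse 1, HC mouse 1) than in the 3 SKY libraries in each of the 5 cell types, with median log2 1.57, 1.30, 1.32, 1.01 and 1.59 in beta, alpha, delta, macrophage and endothelial sums (camera adjusted p = 7.25e-41, 1.94e-33, 3.24e-13, 0.00163 and 0.000119). These had adjusted p = 0.504, 0.361, 0.321, 0.879 and 0.866 with an estimated correlation. HC mouse 2 stood apart from the other SKY mice, with acinar medians of 0.95, 0.75, 1.48, 2.35 and 1.41 over chow mice 2 and 3 in the same order of types. Summed over the acinar list, HC mouse 1 lay below HC mouse 2 in delta (550.4 against 666.2 CPM), macrophage (651.4 against 1388.1) and endothelial sums (523.1 against 671.9). Chow mouse 1 was highest there (734.7, 1802.4 and 2047.2). In beta and alpha cells HC mouse 1 lay above HC mouse 2. In macrophages Try5 was at 119.6 CPM in HC mouse 2, above 58.3 and 34.7 in chow mouse 1 and HC mouse 1. Clps, which encodes colipase, had 1.83 ± 0.184 in beta cells (adjusted p = 0.000609, edgeR). Rps27, a ribosomal protein gene, was lower in FUN by a log2 of -0.90 in beta, -1.04 in delta and -1.39 in endothelial cells (adjusted p = 0.01, 3.3e-10 and 9.1e-08), and Cox7c, a respiratory chain gene, by -0.74 in beta cells (0.000674). In macrophages MHC class II genes were higher in FUN (median 0.64, camera adjusted p = 8.54e-06). That list had adjusted p = 0.301 with an estimated correlation. H2-Eb1 had 0.74 and Cd74 0.75 (adjusted p = 0.00104 and 0.00208), while the chemokine gene Cxcl2 had -1.78 and the immediate-early gene Ier3 -3.12 (0.00207 and 0.00689).

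The interferon genes of endothelial cells were higher in HC mice by a median log2 of 0.75. The list call did not hold with an estimated correlation (camera adjusted p = 0.399). A batch marked by the prefix would not give a difference within each prefix, yet the lower of the 2 within-prefix medians was 0.56. The 10% of cells of each mouse richest in the list do not carry it alone. Without them the median was 0.68 (SE 0.149 over list members, 28 of 28 tested members above 0). A larger share of cells was not tested. Macrophage RNA among the endothelial sums is argued against by the 5 tested macrophage markers, which had a median of -0.09 (2 of 5 above 0). Their spread was not taken into account, so with so few markers it is not excluded. An effect of the HC diet on interferon signalling in islet endothelium is a candidate explanation, which was not tested. With age as a term the median was 0.66 (31 of 32 above 0). That fit cannot separate age from diet, because age follows from prefix and diet (rank 3 in 4 columns). Its age slope comes from FUN against SKY. Within each prefix the HC mouse was younger (7 against 8 weeks in FUN, 9 against 10 in SKY), so age stays open.

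Splitting the mice by prefix called 108, 85, 183, 17 and 67 genes in beta, alpha, delta, macrophage and endothelial cells (edgeR), where diet called 1, 1, 0, 2 and 2. Of the other 8 splits, chow mouse 3 with HC mouse 2 called 38 in macrophages, more than prefix, 29 in delta and 17 in endothelial cells, and the highest in beta and alpha cells called 4 each. At an unadjusted p under 0.05 prefix had the most genes in delta and endothelial cells (837 and 479), but in beta and alpha cells 960 and 636, where HC mouse 1 with chow mouse 3 had 1223 and 1079. In fits without a prefix term, the counts for diet therefore do not stand above those of other splits. With prefix as a term diet called 15, 6, 4, 2 and 6 genes in the same order of types, and the other splits were not fitted that way. A structure that follows the library names shows in beta and alpha cells by adjusted calls alone.

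Genes lower in FUN had short transcripts: 79 of 93 in beta cells were at most 1000 nt, against 18.5% of tested genes. Outside the ribosomal and respiratory chain families, genes of at most 1000 nt differed from longer ones by a median log2 of -0.024 in beta cells (SE 0.012), -0.038 (0.01) in alpha, -0.045 (0.012) in delta, -0.071 (0.03) in macrophage and -0.086 (0.02) in endothelial cells. This argues against a general length trend of more than 0.1 in all 5 types, while a smaller one is not excluded. A loss of fragments under 500 nt may contribute. That comparison included the ribosomal and respiratory chain families, so its values cannot be set beside those for 1000 nt. Genes of at most 500 nt lay lower by more than 2 SE in alpha (-0.148, SE 0.047), delta (-0.149, 0.053), macrophage (-0.428, 0.09) and endothelial cells (-0.264, 0.075). In beta cells they did not (-0.095, 0.048). The 2 families may make these values, so the loss of fragments stays open. Age could be another cause, but 0 ages in weeks are shared by mice of both prefixes.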
